A study of Homo sapiens with 4 samples.

How the data were processed

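RNA was sequenced from 4 libraries of Daoy cells, 2 infected with pLKO control virus and 2 with shFABP4 virus, and groups were taken from the sample labels. Per the labels' protocols, RNA was prepared with TRIzol, mRNA was enriched with capture beads and fragmentation used Tn5. FastQC, HISAT and StringTie and the build GRCh38 are named in the submitters' processing notes, without versions. The authors deposited raw counts of fragments per gene name, made with featureCounts v2.0.0 and the GENCODE 38 annotation, per the file headers. Per the file headers, fragments were counted over exons by gene name, chimeric fragments were left out, and no strand option was set. Without strand, a gene cannot be separated from an overlapping or antisense partner, and near-identical paralogs or pseudogenes can share fragments. The exon length of each gene name was also taken from the deposited table. Counting by name merges loci that share a name. The labels do not say whether libraries were treated with DNase, and no reads were analysed here.

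The table held 59384 gene names with 4 readable counts. The gene ANK2 was left out because its row was broken over 7 lines, 4 of them blank. All 37 mitochondrial gene names held 0 in every library. Gene types and GC content came from GENCODE 29, to which 63.6% of gene names matched, 99.1% of these overlapping the same position, and 91.5% of genes with a mean of at least 20 counts had a GC value. Depth ranged from 2539862 to 20431660 fragments per library. The limit that a count of 0 allows was set at 3 counts, and Poisson intervals are exact at 95%. The pLKO libraries differed by more than sampling noise (chi-square per degree of freedom 2.16 over 13291 genes, against 197 between pLKO 1 and shFABP4 2), and were kept as 2 samples.

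Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and total of 15, robust quasi-likelihood F test, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. With 2 libraries against 2, an exact permutation test cannot reach p = 0.05. Lists were tested with camera and fry in limma 3.58.1 on log2 CPM with a prior count of 2, for lists with at least 5 tested members. Camera used a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative. There were 50 lists with 1182 genes, 1180 of them in the table. CPM are counts scaled to the library total, and normalised CPM use TMM-scaled totals.

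Genes were named by a rule set beforehand. It took FABP4 and the detected FABP family, and the 10 largest changes in each direction among genes past the threshold with a mean of at least 20 counts and both shFABP4 libraries on the same side of both pLKO libraries. Because 0 genes passed, the 10 smallest p in each direction were named as not passing. For each lipid, growth and called list the 2 members with the smallest p were named, where the rule allowed up to 4. A few items that the rule names are not reported here. PTCH1, BOC and the list members named among high-signal genes were chosen after their values were seen. The same rule, of size and of side against the pLKO libraries, was used for the 19 high-signal genes named first. The rule left out pseudogenes, antisense RNAs and clone-type names. GPX1, typed as a polymorphic pseudogene in GENCODE 29 but as coding in RefSeq, was at first left out by a coding error and was added after its values were seen.

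Background in shFABP4 1 was estimated from 2761 coding genes with no fragment in the other 3 libraries, as fragments per kb in 6 bins of GC content. High-signal genes were coding genes whose expected RNA fragments in shFABP4 1 were at least 5 times that background. The expected RNA came from the mean share over the other 3 libraries, shFABP4 2 included. The background estimate leaves 44.6% of the library for RNA, while high-signal genes imply 22.7%. Both estimates differ, so the set is approximate. The set, the multiples of 2, 5 and 10, a background rate by length only, the subtraction of background, the high-signal scaling of other named genes and the correction for GC content and length (splines with 4 degrees of freedom per library) were chosen after seeing the data.

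The gene test was tried on simulated data drawn from the real means and depths with 200 changed genes. With all 4 libraries over 14735 genes, 0 of 200 were recovered at a fold of 4 and 41 at a fold of 16, with 1 false call. Without shFABP4 1, 93 of 200 were recovered at a fold of 1.5 with 5 false calls. Among high-signal genes 200 of 200 were recovered at a fold of 4 with 8 false calls. Camera was tried once, on independent normal noise over the genes tested with all 4 libraries, with the G2/M genes raised in shFABP4. It called that list and no other. Such noise holds no correlation between genes, so this trial does not show how camera behaves with correlated genes.

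Alternatives were each library left out in turn, the replicate number as a block, no filter and a stricter filter, 3 other scalings, DESeq2 1.42.0, limma-voom, a non-robust spread, protein-coding genes only, stricter thresholds, and camera on ranks. With a library left out the lone library of its group is assumed to vary like the other group. Alternatives planned for FPKM or TPM values were not run because counts were deposited. Mitochondrially encoded genes and lists with under 5 tested members were left out of the list test.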

Results

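Gene expression was measured by RNA sequencing in Daoy cells, an established human medulloblastoma line. The cells had been infected with a lentivirus carrying a short hairpin against FABP4 (shFABP4) or with the pLKO control virus. FABP4 is a small cytosolic protein that binds fatty acids and is best known from adipocytes. Each group held 2 libraries, numbered 1 and 2 by the labels. The single comparison and its lists of genes were chosen before the data were examined. Nothing states that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The pLKO libraries held 8988961 and 13839885 counted fragments. The shFABP4 libraries held 2539862 (library 1) and 20431660 (library 2).

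The libraries differed in makeup as well as in depth. A fragment was counted in 23372 and 25560 gene names in the pLKO libraries and in 22350 in shFABP4 2, but in 51762 gene names in shFABP4 1, the shallowest library. Olfactory receptor genes, which encode odorant receptors of the nasal epithelium, carried 0.213 and 0.354 fragments per kb of exon in the pLKO libraries, 0.222 in shFABP4 2 and 6.55 in shFABP4 1. A fragment was present in 368 of 381 such genes in shFABP4 1 and in 38 to 68 of them in the other libraries. Coding genes with no fragment in the other 3 libraries gave a background rate for shFABP4 1, from 3.46 fragments per kb at under 40% GC to 18.4 above 60% GC. At those rates background made up 55.4% of the fragments of shFABP4 1 and 45.5% of those in the genes tested below. Over the tested genes, log2 values correlated at r = 0.987 between the pLKO libraries, at 0.895 and 0.899 between shFABP4 2 and the pLKO libraries, and at 0.544 to 0.559 between shFABP4 1 and the others, across genes that are not independent replicates.

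**Figure D1:**
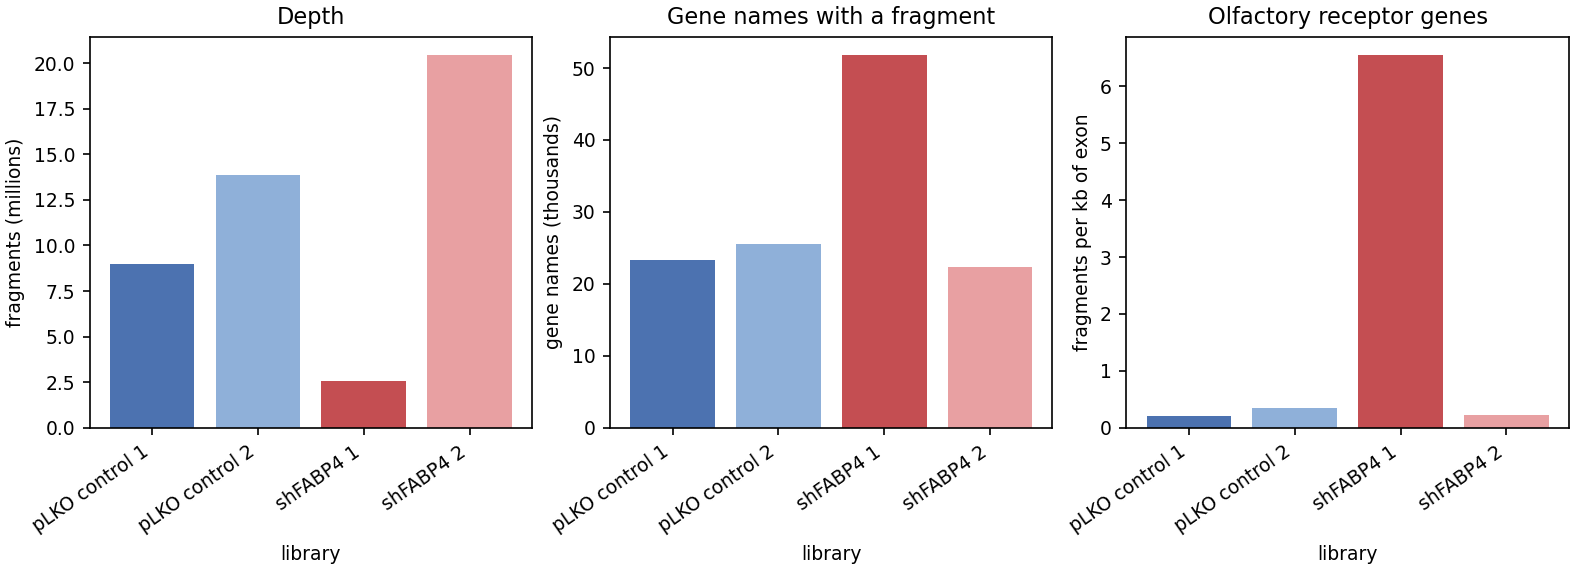
Bars give, for each of the 4 libraries, the counted fragments, the gene names with at least 1 fragment, and the fragments per kb of exon over 381 olfactory receptor genes. shFABP4 1 has the fewest fragments, 2539862, the most gene names, 51762, and the highest olfactory receptor rate, 6.55 per kb.

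FABP4 itself, the targeted gene, was barely detected. Its locus lies on chromosome 8 from 81478419 to 81483236 (GRCh38, minus strand), with 1369 bases of merged exons. The pLKO libraries held 1 and 6 FABP4 fragments, shFABP4 1 held 14 and shFABP4 2 held 0. As counts scaled to the library total (CPM) this was 0.111 (95% Poisson interval 0.00282 to 0.620), 0.434 (0.159 to 0.944), 5.51 (3.01 to 9.25) and 0, where a count of 0 allows up to 0.147. These intervals cover counting error only. For shFABP4 1 the background rates predict 4.74 FABP4 fragments at the gene's GC content, or 11.8 at the mean rate of coding genes. FABP4 failed the low-count filter. Its value in the library labelled shFABP4 1 lay above both pLKO values, against the label, so these counts do not check that label and do not settle whether FABP4 was lowered. Fisher's exact test (two-sided) of 7 FABP4 fragments among 22828846 in the pLKO libraries against 0 in shFABP4 2 gave p = 0.0166, which compares those libraries and not the conditions.

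**Figure D2:**
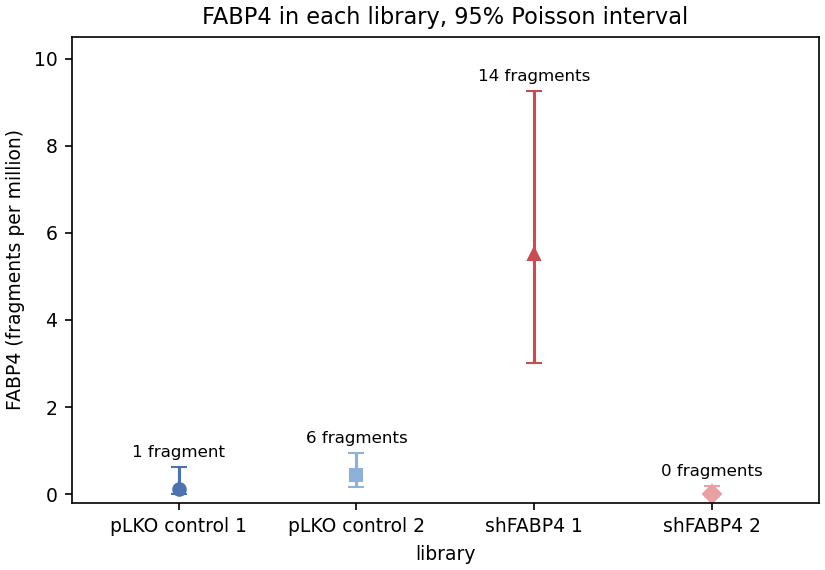
Points give FABP4 CPM in each library, with exact 95% Poisson intervals and the number of fragments. The pLKO libraries hold 1 and 6 fragments, shFABP4 1 holds 14 and shFABP4 2 holds 0.

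Among the other fatty acid binding proteins, FABP5 was the only member with more than 20 fragments in any pLKO library, at 174 and 259, against 48 in shFABP4 1 and 1121 in shFABP4 2. Scaled to the library, FABP5 was at 26.0 ± 0.508 normalised CPM (SD, n = 2) in pLKO and 37.9 ± 35.9 (SD, n = 2) in shFABP4. Its log2 fold change was 0.55 (SE 0.87, adjusted p = 0.744, edgeR), and with this scaling the 2 shFABP4 libraries lay on opposite sides of the pLKO libraries (-2.25 without shFABP4 2, 1.29 without shFABP4 1). The side of shFABP4 1 turned with the scaling. As plain CPM it lay between the pLKO libraries (18.9 against 19.4 and 18.7), and scaled by the abundant genes described below both shFABP4 libraries lay above (112 and 97.2 against 32.0 and 30.9, or 81.6 in shFABP4 1 with its expected background subtracted). Among genes above 2 times the background, a set chosen after the data had been seen, FABP5 rose by 1.54 (adjusted p = 0.0241, edgeR). Its pLKO values alone would not have placed FABP5 in that set, which it entered through its high value in shFABP4 2. That call is therefore not independent support for a rise. FABP3, the heart form, had 6 and 20 fragments in pLKO and 18 and 0 in shFABP4 (adjusted p = 0.897, edgeR). FABP6 had 5 and 1 fragments in pLKO and 26 and 0 in shFABP4. FABP1, FABP2, FABP7, FABP12 and PMP2 had no fragment outside shFABP4 1, where 33, 6, 7, 4 and 7 were counted against 15.9, 7.71, 11.1, 2.74 and 12.2 expected from background.

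The comparison of shFABP4 with pLKO asks which transcripts differ once FABP4 is targeted in a medulloblastoma line, a study framed around tumour growth. Of 14735 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05. The smallest adjusted p was 0.391, shared by the genes named here as not passing. An unadjusted p under 0.05 was reached by 1818 genes (1187 higher and 631 lower in shFABP4), where 737 are expected by chance. DESeq2 called 548 genes higher and 171 lower, and limma-voom called 0. The estimated coefficient of variation between replicates was 0.683, and in counts simulated at that spread the test recovered 0 of 200 genes changed 4-fold and 41 of 200 changed 16-fold.

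The genes with the smallest p among those higher in both shFABP4 libraries included SPARC, MATN2, NR1D1, CYP24A1, OS9, PLPP3, EIF3L, TMED1 and OLFML2A. SPARC, a secreted matrix glycoprotein, had 2 and 2 fragments in pLKO and 47 and 376 in shFABP4. CYP24A1, which inactivates vitamin D, had 0 and 1 against 37 and 204, and NR1D1, a repressor of the circadian clock, had 5 and 3 against 99 and 414. None of these 9 had more than 49 fragments in a pLKO library. In shFABP4 1 their counts were 0.976 to 2.41 times the expected background (47 SPARC fragments against 48.2 expected). The 10 with the smallest p among those lower were TMEM256, ADCK2, ALYREF, SNHG19, APOH, C1orf216, WDR76, TMEM11, AP1M2 and PATJ-DT. ALYREF, an mRNA export adaptor, had 2449 and 3701 fragments in pLKO and 77 and 341 in shFABP4, where 24.7 were expected from background in library 1. APOH, a plasma glycoprotein, had 981 and 1470 against 56 and 127. In shFABP4 1 ADCK2 held 32 fragments against 48.5 expected from background, C1orf216 37 against 31.6 and PATJ-DT 1 against 3.67, while SNHG19 held 70 against 5.33. When scaled by the abundant genes described below, ADCK2, WDR76 and TMEM11 lay above both pLKO libraries in shFABP4 1 and AP1M2 lay between them. TMEM256, ALYREF, SNHG19, APOH, C1orf216 and PATJ-DT stayed below, as did all 10 once background was also subtracted. At that scaling without subtraction, ALYREF was at a log2 fold change of -2.36 (SE 0.96, adjusted p = 0.130, edgeR). APOH was at -1.82 (SE 1.29, adjusted p = 0.316, edgeR). Over all tested genes they were at -4.23 and -3.77.

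The 2 shFABP4 libraries give separate answers when taken singly. Without shFABP4 2 the filter kept 27830 genes, and that fit rests on shFABP4 1 with its background. With shFABP4 1 left out, 10242 of 15301 genes were called (5238 higher, 5004 lower). The spread then comes from the pLKO libraries alone, whose coefficient of variation was 0.0434, and shFABP4 2 is assumed to vary as little. With shFABP4 2 left out, 23895 genes were called (15744 higher, 8151 lower).

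Transcripts abundant enough to stand above the background of shFABP4 1 were examined separately, in a set defined after the data had been seen. It held the 1020 coding genes whose expected RNA fragments in shFABP4 1, predicted from the other 3 libraries, were at least 5 times the expected background (high-signal genes). The multiple of 5 and every alternative to it were also chosen after the data had been seen. The prediction drew on shFABP4 2 as well as on the pLKO libraries, so a gene could enter the set through a high value in shFABP4 2. Increases were not retested in a set chosen from the pLKO libraries alone. In these genes 184 rose and 170 fell in shFABP4 at an adjusted p under 0.05 (edgeR). The largest increases were in TMSB4X, which encodes the actin-sequestering thymosin beta 4 (log2 fold change 3.46, SE 0.37, adjusted p = 0.0132), and BASP1, a membrane-bound protein of growth cones (3.29, SE 0.58, adjusted p = 0.0262). Large decreases were in ANGPTL4, a secreted inhibitor of lipoprotein lipase (-3.71, SE 0.15, adjusted p = 0.0113), in GPX1, a glutathione peroxidase (-3.39, SE 0.20, adjusted p = 0.0113), and in EIF5A, a translation factor (-3.23, SE 0.17, adjusted p = 0.0113). ANGPTL4 had 2970 ± 17.3 normalised CPM in pLKO and 227 ± 10.8 in shFABP4 (SD, n = 2 each). In shFABP4 1 it held 94 fragments, with 45.5 expected from background. With background subtracted it lay at 114 in shFABP4 1, against 234 in shFABP4 2, so the small SD in shFABP4 includes background.

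The other large increases were in PRDX3, a mitochondrial peroxidase (2.66), PCNP (2.61), ALDH1A1, a retinaldehyde dehydrogenase (2.58), HNRNPF (2.31), YWHAB (2.30), RAB1A (2.28), RTN4 (2.24) and EEF1A1, the main translation elongation factor (2.22), as log2 fold changes with adjusted p from 0.0113 to 0.0310 (edgeR). By their pLKO shares alone PRDX3, PCNP, HNRNPF, RAB1A and RTN4 would not have reached 5 times the background. They entered the set through their high value in shFABP4 2, so the selection favoured their increases and these calls are not independent support. Further large decreases were in TMEM256 (-2.77), the neutrophil chemokine CXCL5 (-2.71), the metallothionein MT2A (-2.64), CYBA (-2.42), MRPL41 (-2.31) and NDUFA13 (-2.30), with adjusted p from 0.0113 to 0.0498. Counting ignored strand, and TMSB4X and EEF1A1 have many near-identical pseudogenes, so their values are less certain. CXCL5 was at 349 ± 6.68 normalised CPM in pLKO and at 53.3 ± 0.440 in shFABP4 (SD, n = 2 each). In shFABP4 1 that rested on 23 CXCL5 fragments, with 8.44 expected from background, so the SD of 0.440 understates the error. There TMEM256 held 25 fragments against 10.4 expected and NDUFA13 88 against 49.8, while MT2A held 1931 against 14.3. MT2A was at 25982 and 25658 in pLKO and at 4501 and 3766 in shFABP4. Genes that rose had a median GC content of 46.5%, those that fell 58.4% and those not called 54.1%. After correction for GC content and transcript length 16 of these 19 genes passed. The other 3 kept their direction with smaller log2 fold changes at a similar SE and no longer passed: YWHAB went from 2.30 (SE 0.44) to 1.88 (SE 0.46, adjusted p = 0.0658), TMEM256 from -2.77 (SE 0.68) to -2.22 (SE 0.64, 0.0863) and NDUFA13 from -2.30 (SE 0.48) to -1.84 (SE 0.47, 0.0712). High-signal genes took 62.0% of the fragments in pLKO, 59.6% in shFABP4 2 and 15.2% in shFABP4 1.

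**Figure D3:**
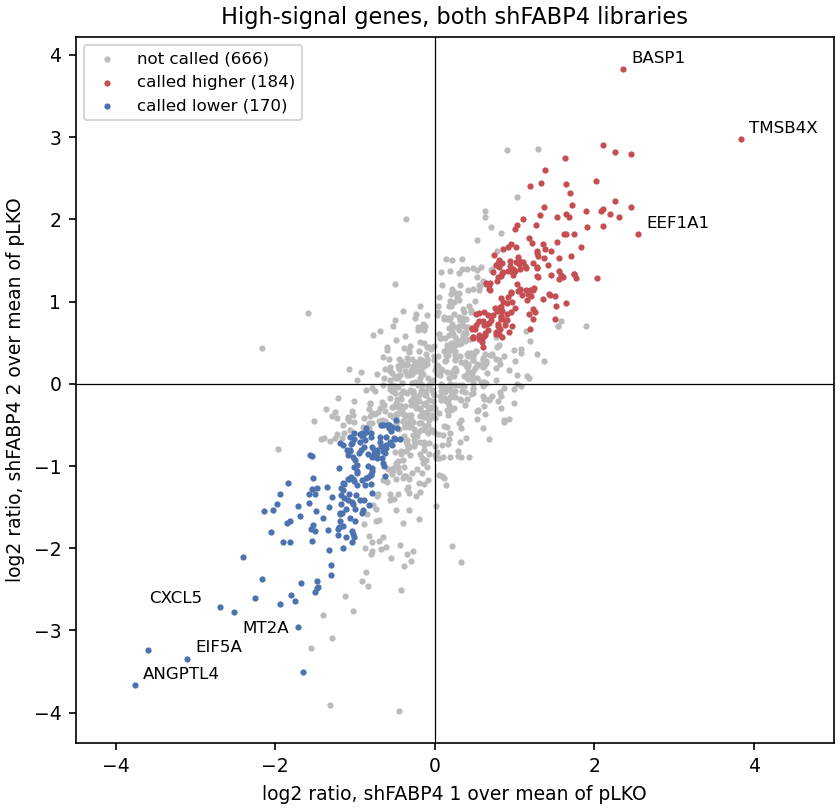
Each point is 1 of the 1020 high-signal genes, with the log2 ratio of shFABP4 1 to the mean of the pLKO libraries on the horizontal axis and that of shFABP4 2 on the vertical axis. Of these genes 80.8% have the same sign in both ratios, which share the pLKO libraries. The set was chosen partly by shFABP4 2. The called genes (184 higher, 170 lower) are coloured.

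**Figure D4:**
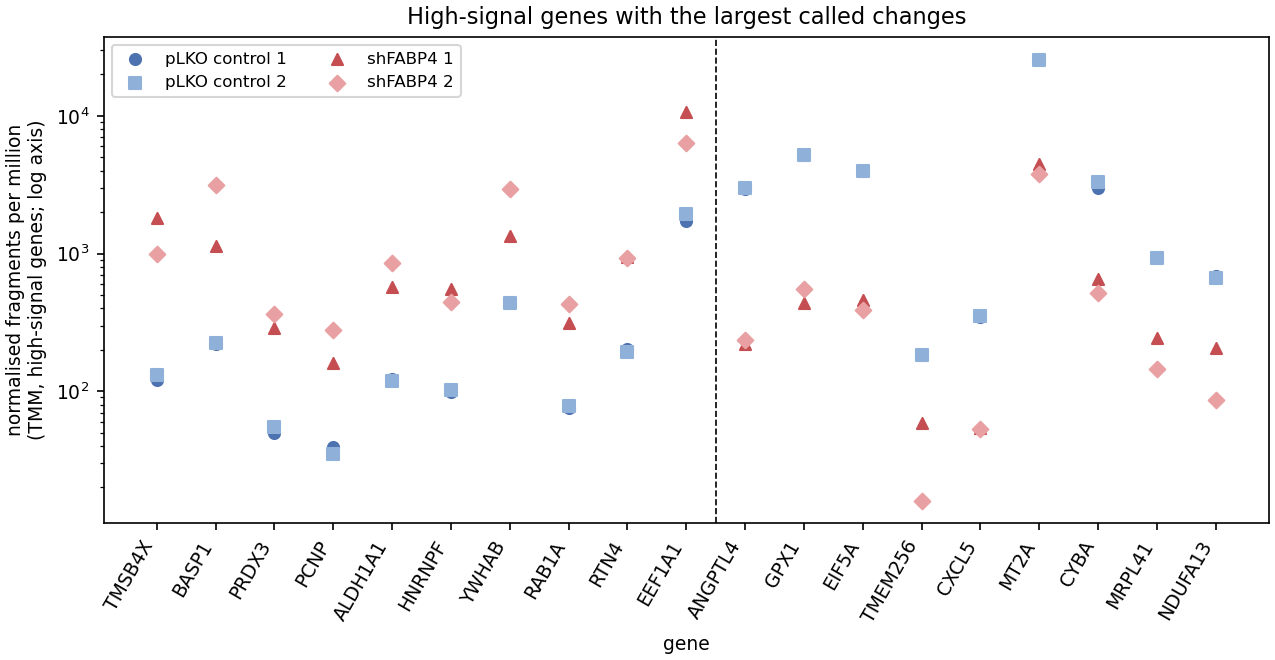
Points give normalised CPM (TMM among high-signal genes, log axis) in each of the 4 libraries for the 10 largest called increases (left of the dashed line) and 9 of the largest called decreases (right). Genes were chosen to have both shFABP4 libraries on the same side of both pLKO libraries. ANGPTL4, for example, lies at 2958 and 2982 in pLKO and 219 and 234 in shFABP4.

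The number of these calls hangs on the scaling and on the pLKO pair. With libraries scaled by all of their fragments, background included, 0 of the 1020 genes passed in edgeR (96 at an unadjusted p under 0.05, against 516 before), and the median log2 fold change moved from -0.02 to -0.74. The share of calls that were increases was 52.0%, against 65.7% with upper-quartile scaling. DESeq2 called 464 of the 1020. With either pLKO library left out 114 to 116 genes passed, with either shFABP4 library left out 789 to 939, and after correction for GC content and transcript length 226 passed, 169 of them in both fits with the same direction.

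The lists of genes for lipid handling are described first, with log2 medians relative to a median of 0.34 over all tested genes. That median was 0.26 with RLE, 0.57 with upper-quartile and 1.30 with total-count scaling. With camera at a preset inter-gene correlation of 0.01, 1 of the 5 lipid lists that could be tested passed. Cholesterol biosynthesis was lower (median -0.70 relative to all genes, adjusted p = 0.0124), with both shFABP4 libraries below both pLKO libraries for 9 of 23 members and above for 3. Its adjusted p was 0.754 with an estimated correlation. MVK, mevalonate kinase, had 185 ± 3.92 normalised CPM in pLKO and 57.7 ± 6.39 in shFABP4 (SD, n = 2 each). It did not pass singly, and in shFABP4 1 it held 204 fragments against 119 expected from background. Scaled by the high-signal genes, MVK in shFABP4 1 lay above the pLKO libraries (476 against 228 and 220). With background also subtracted it lay below them (198). PPAR targets (12 members, adjusted p = 0.719), fatty acid oxidation (23, 0.449), fatty acid synthesis (22, 0.449) and lipid storage and uptake (20, 0.348) did not pass in camera. The first, second and last of these had fitted medians above 0 (0.19, 0.14 and 0.04) but medians of log values below 0 (-0.14, -0.16 and -0.18), and camera placed them lower. In those 4 lists and in cholesterol biosynthesis 0 members passed over all genes tested, and 0 adjusted over the list alone. The FABP family had 2 tested members, FABP5 and FABP3, too few for the list test.

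Among high-signal genes 3 lipid genes passed (named because few did, after their values were seen). ANGPTL4, a PPAR target, fell as above. SCD, which makes monounsaturated fatty acids, rose by 1.36 (SE 0.13, adjusted p = 0.0119), and ECI1, an isomerase of fatty acid oxidation, by 0.66 (SE 0.14, adjusted p = 0.0332, edgeR). ECI1 lay at -0.01 when scaled by all fragments. All 3 passed after correction for GC content and length (adjusted p from 0.0192 to 0.0246).

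Growth lists moved mostly towards lower values in camera, and 4 of 5 passed. G1/S genes were lower (median -1.07 relative to all genes, adjusted p = 0.000494), with both shFABP4 libraries below both pLKO libraries for 20 of 39 members. G2/M genes (-0.67, adjusted p = 0.00311, 19 of 39) and MYC targets and ribosome biogenesis (-1.17, adjusted p = 0.00120, 19 of 31) were lower too. The Hedgehog pathway was higher (1.46, adjusted p = 0.00469), with 10 of 18 members above both pLKO libraries. With the background of shFABP4 1 subtracted it did not pass (adjusted p = 0.178), and its median difference of log2 CPM, relative to all genes, went from 1.07 to 0.38. Cyclins and CDK inhibitors did not pass (adjusted p = 0.181). Each of these 5 lists had an adjusted p of 0.754 with an estimated correlation, and 0 of their members passed over all genes tested or adjusted over the list alone. By chance, both libraries of a group lie above both of the other for 16.7% of genes, against 28.5% of all tested genes observed above and 26.1% below.

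The CPM values of named list members used TMM over all tested genes, which counts the background of shFABP4 1. Members with the smallest p included E2F1, a transcription factor of S-phase entry, at 328 ± 0.0861 normalised CPM in pLKO and 37.1 ± 12.7 in shFABP4 (SD, n = 2 each), and CCNE1, cyclin E1, at 120 ± 7.07 and 28.3 ± 4.92. CDK2 was at 74.0 ± 4.33 and 13.0 ± 1.81, the mitotic kinase AURKB at 314 ± 12.8 and 42.9 ± 19.7, and the midzone protein PRC1 at 40.2 ± 6.33 and 13.1 ± 0.0469. In shFABP4 1, CDK2 held 45 fragments against 40.3 expected from background and PRC1 50 against 36.3, so their values there are mostly background. E2F1 held 108 against 49.4, CCNE1 122 against 25.5 and AURKB 111 against 34.9. With TMM among high-signal genes AURKB was at 379 ± 14.2 in pLKO and 173 ± 121 in shFABP4 (SD, n = 2 each), a log2 fold change of -1.24 (SE 0.58, adjusted p = 0.167) against -2.87 over all tested genes. At that scaling, with background subtracted, CCNE1 in shFABP4 1 lay above the pLKO libraries (224 against 140 and 151). The ribosome biogenesis genes PPAN and NOP16 followed among the members with the smallest p. PPAN had 872 and 1284 fragments in pLKO and 26 and 299 in shFABP4, and NOP16 had 789 and 1159 against 90 and 591, with 53.1 and 29.2 expected from background in library 1. With background subtracted at the high-signal scaling, NOP16 in shFABP4 1 lay between the pLKO libraries (142 against 145 and 138). GLI1, a transcription factor and target of Hedgehog signalling, had 49 and 72 fragments in pLKO and 123 and 479 in shFABP4, with 71.1 expected from background in library 1. SFRP1 had 6 and 16 against 64 and 942, with 31.1 expected.

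With shFABP4 1 left out, 0 growth lists and 0 lipid lists passed. In shFABP4 2 against the pLKO libraries G1/S genes had 8 members called higher and 24 lower, and G2/M genes 17 and 16. Among high-signal genes CCNB1 (cyclin B1) rose by 0.85 (SE 0.14, adjusted p = 0.0220) and DLGAP5 by 0.71 (SE 0.17, adjusted p = 0.0473), while CDC20 fell by 0.92 (SE 0.20, adjusted p = 0.0382) and CCND3 (cyclin D3) fell by 1.56 (adjusted p = 0.0163), as log2 fold changes from edgeR. Of the MYC list NPM1, NOP58, HSPE1 and DDX21 rose (1.34, 1.35, 1.11 and 0.99, with SE 0.27 for NPM1 and 0.24 for DDX21) and SRM fell by 1.31 (SE 0.18). These genes were named after their values were seen. After correction for GC content and length CCND3, NOP58 and HSPE1 passed. The others did not, with smaller log2 fold changes: CCNB1 0.21 (SE 0.11, adjusted p = 0.229), DLGAP5 0.03 (SE 0.16, 0.883), CDC20 -0.63 (SE 0.22, 0.114), NPM1 0.68 (SE 0.29, 0.172), DDX21 0.49 (SE 0.19, 0.149) and SRM -0.61 (SE 0.22, 0.128).

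Over all lists, camera called 16 of 44, 3 higher and 13 lower in shFABP4. The third list that was higher beside the Hedgehog pathway and the SHH medulloblastoma markers was extracellular matrix (adjusted p = 0.00556), with 13 of 22 members above both pLKO libraries and SPARC and COL1A1 passing adjusted over the list alone. With background subtracted it did not pass (adjusted p = 0.230), and its median difference of log2 CPM, relative to all genes, went from 0.93 to 0.27. Its adjusted p was 0.754 with an estimated correlation, as was that of the SHH medulloblastoma markers. COL1A1, the main fibrillar collagen chain, had 41 and 55 fragments in pLKO and 585 and 1033 in shFABP4. The SHH medulloblastoma markers (adjusted p = 0.00118) had 5 of 6 members passing adjusted over the list alone and 0 over all genes tested, with PTCH1 at 9 and 14 fragments in pLKO and 221 and 134 in shFABP4 (178 expected from background in library 1). In shFABP4 2 alone, 5 of the 6 SHH markers were called higher, and BOC was not.

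The lists that were lower besides those above were nuclear oxidative phosphorylation subunits (adjusted p = 8.06e-07, 32 of 55 members below both pLKO libraries and 0 above), proteasome (0.000494), cytosolic ribosomal proteins (0.00120), heat shock genes (0.00202), p53 targets (0.00302), apoptosis regulators (0.00469), autophagy and lysosome (0.0208), NF-kB inflammatory genes (0.0390) and ferroptosis regulators (0.0439). With an estimated correlation the adjusted p was 0.784 for ribosomal proteins and 0.754 for each of the other 15 lists. The 28 other lists tested had adjusted p from 0.0579 to 0.963. Among the 2 members of each list with the smallest p were NDUFB8, a complex I subunit (345 ± 5.14 normalised CPM in pLKO, 32.6 ± 22.5 in shFABP4), the pro-apoptotic BAX (399 ± 0.389 and 42.3 ± 28.9), the HSP90 cochaperone AHSA1 (158 ± 15.5 and 24.3 ± 4.38) and PSMD2 (830 ± 8.95 and 110 ± 64.0), each SD with n = 2. With TMM among high-signal genes the decreases were smaller, at log2 fold changes of -2.00 (SE 0.38, adjusted p = 0.0310) for NDUFB8, -1.80 (SE 0.39, 0.0385) for BAX and -1.34 (SE 0.48, 0.102) for PSMD2, against -3.40, -3.23 and -2.92 over all tested genes. After correction for GC content and length NDUFB8 (-1.67, SE 0.36, adjusted p = 0.0520) and BAX (-1.17, SE 0.35, 0.0901) no longer passed. AHSA1 is not a high-signal gene. At that scaling, with background subtracted, it lay between the pLKO libraries in shFABP4 1 (200 against 205 and 177). IL11, in the NF-kB list, went the other way, at 55 and 72 fragments in pLKO and 240 and 681 in shFABP4.

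**Figure D5:**
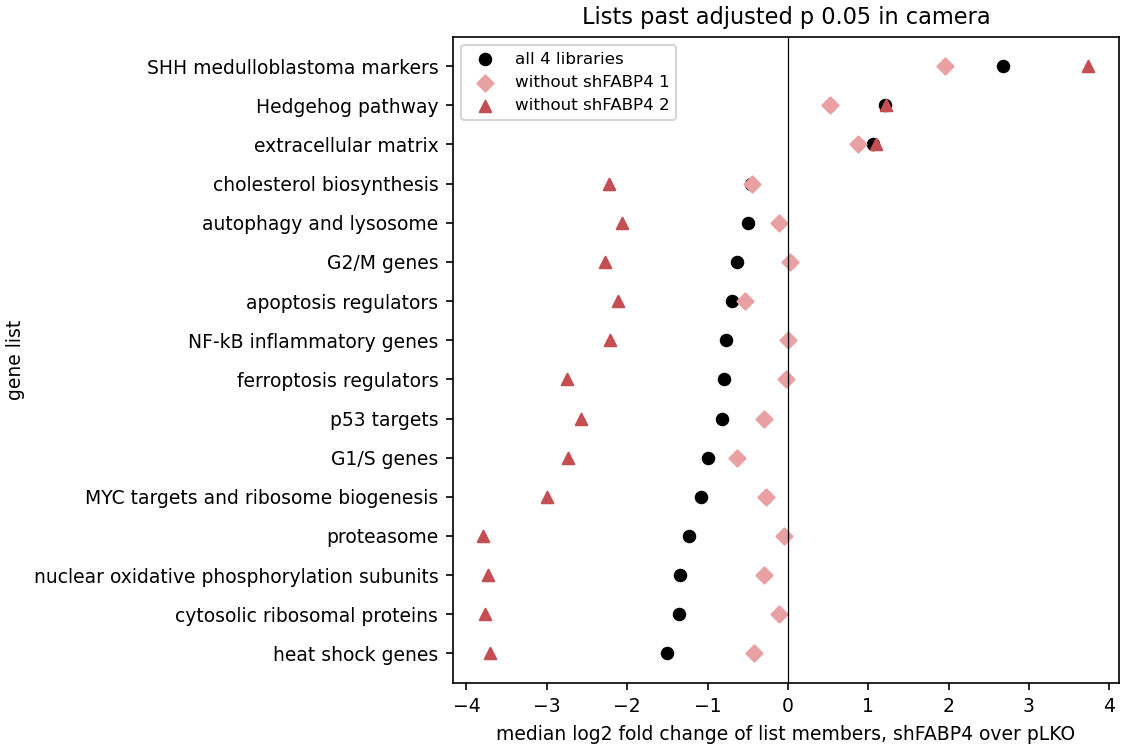
Points give the median difference of log2 CPM of list members, shFABP4 over pLKO, for the 16 lists that passed camera, with all 4 libraries, without shFABP4 1 and without shFABP4 2. Nuclear oxidative phosphorylation subunits lie at -1.34 with all libraries, -0.30 without shFABP4 1 and -3.73 without shFABP4 2.

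These list results moved with the library left out. With shFABP4 1 left out 1 list of 45 passed, and with shFABP4 2 left out 32 of 49 passed, all lower. With the background of shFABP4 1 subtracted 8 of the 16 lists no longer passed, the Hedgehog pathway and extracellular matrix as above and 6 lower lists. Of these, the median difference of log2 CPM, relative to all genes, shrank for G2/M genes (-0.76 to -0.01, adjusted p = 0.189), ribosomal proteins (-1.49 to -0.36, 0.0528), cholesterol biosynthesis (-0.59 to -0.31, 0.0528) and autophagy and lysosome (-0.63 to -0.29, 0.174). It stayed about as large or grew for ferroptosis regulators (-0.93 to -0.85, 0.0656) and NF-kB inflammatory genes (-0.91 to -1.27, 0.202). Camera does not test the median, and why those 2 lists no longer passed was not tested. Among high-signal genes camera passed 0 of 16 lists. In that set 1 list, the ribosomal proteins, had an unadjusted p under 0.05. They were higher, with a median fitted log2 fold change of 0.32, opposite to their call over all genes. There, 10 of 41 oxidative phosphorylation genes rose and 5 fell, and 13 of 73 ribosomal protein genes rose and 6 fell. Ribosomal protein genes have many pseudogenes, which makes their counts less certain.

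Of the markers of other cell types, a fragment was counted in shFABP4 1 for 14 of 14 myeloid, 12 of 12 lymphocyte, 10 of 10 endothelial, 22 of 22 neuronal, 14 of 14 glial and 14 of 14 adipocyte genes. In shFABP4 2 the corresponding numbers were 5, 6, 6, 16, 7 and 10. Scaled to the library total, each of these 6 lists was highest in shFABP4 1, from 4.71 CPM per kb for glial to 8.30 for endothelial markers. Endothelial markers were at 5.71 and 5.83 in pLKO and 4.02 in shFABP4 2. The epithelial keratins KRT8, KRT18 and KRT7 were abundant in every library, KRT7 at 17168 and 26027 fragments in pLKO and 1388 and 75350 in shFABP4. All 37 mitochondrial gene names stood at 0 in every library, so the mitochondrially encoded list was not tested.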

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

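All tests in this part were chosen only after the result was seen. Olfactory receptor genes, which no comparison uses, carried 6.546 fragments per kb of exon in shFABP4 1, above the 0.213 and 0.354 of the control libraries and the 0.222 of shFABP4 2.

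This signal belongs to a wider pattern, fragments in most gene names of shFABP4 1. Of 28874 gene names at 0 in the other 3 libraries, 21908 held a fragment there. Shallower sequencing does not give this, since the other libraries thinned to 2539862 fragments held at most 18561 gene names against 51762. RNA from another cell type, as the only source, would favour the markers of that type. At least 96.59% of the members of each of 5 marker lists (myeloid, lymphocyte, endothelial, neuronal and adipocyte) and of the olfactory receptors held a fragment. With fragments in most gene names, presence cannot show whether such RNA lay on top of the background. The 5 lists carried 12.8 to 21.1 fragments per kb in shFABP4 1, against 8.58 for silent coding genes, without matching for GC content. Genomic DNA in the library is a candidate source, as a hypothesis: olfactory receptors carried 1.213 times the fragments expected from other silent coding genes of the same GC content. Apart from RNA of another cell type as the only source, no biological explanation was tested for this pattern.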

How the results depend on the processing

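The high-signal set, its alternatives, the summed pLKO libraries, the subtraction of background and the GC and length corrections were chosen after seeing the data. The depth and background of shFABP4 1 limit all results that use it. With 0 genes called, RLE, upper-quartile and total-count scaling, the stricter filter, limma-voom, a non-robust spread and protein-coding genes only also called 0.

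The count of genes changed ranged from 0 to 23895 with 1 library left out, where the spread comes only from the pair of the other group. It was 69 with no filter, 719 with DESeq2, 354 in high-signal genes, 514 above 2 times and 219 above 10 times the background, and 9211 without shFABP4 1 after GC and length correction. Among high-signal genes the count (354) ranged from 114 to 939 with 1 library left out. It was 117 with the pLKO libraries summed, 226 after GC and length correction, 219 at 10 times the background, 208 with a background rate by length only and 0 when scaled by all fragments. Apart from fewer genes or libraries, the cause was not tested.

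The replicate numbers do not pair the libraries by any label, and the deviations of same-numbered libraries correlated at 0.0106 across tested genes and at 0.152 across high-signal genes, which are not independent. With the replicate block 28 genes were called (24 higher, 4 lower), the high-signal count was 449 and the FABP3 log2 fold change was -1.16.

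The difference in mean FABP4, 1.45 normalised CPM in shFABP4 over pLKO, was 3.63 with total-count scaling and 0.562 with no filter. It ranged from -0.289 without shFABP4 1 to 1.52 without shFABP4 2, was 0.490 without pLKO 1, and changed direction when shFABP4 1 was left out. FABP5 (0.55) ranged from -2.25 without shFABP4 2 to 1.29 without shFABP4 1 and was -0.00276 in limma-voom. FABP3 (0.57) ranged from -7.13 without shFABP4 1 to 0.49 without pLKO 2, was -0.63 without pLKO 1, -0.34 with no filter, -2.76 in limma-voom and -7.18 without shFABP4 1 after GC and length correction. FABP3 is near the floor in shFABP4 2, so these folds depend on the prior count.

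Of 44 lists 16 passed. With 1 library left out this ranged from 1 to 32. It was 34 with no filter, 0 with an estimated correlation, 0 in fry, 9 with background subtracted and 0 among high-signal genes. Lipid lists (1 passed) ranged from 0 to 3 with 1 library left out, and were 4 with no filter, 0 with the stricter filter, 0 with an estimated correlation, 0 in fry and 0 with background subtracted. Growth lists (4 passed) ranged from 0 to 5, and were 0 with an estimated correlation, 0 in fry, 2 with background subtracted and 0 among high-signal genes. Extracellular matrix tested lower without shFABP4 2 (median 1.09, adjusted p = 0.745), and its median ranged from 0.87 without shFABP4 1 to 1.19 without pLKO 2. Among high-signal genes the median differences of log2 CPM of ferroptosis regulators (0.38), oxidative phosphorylation subunits (0.16), ribosomal proteins (0.26) and MYC targets (0.64) lay above 0. The cause was not tested. Rank-based camera and the stricter filter passed 15 and 14 lists.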

Other observations

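The GC and length corrections, the calls among high-signal genes, and the correlations, simulations and counts of shared calls for both shFABP4 libraries were chosen only after the result was seen. The list tests and the count of genes without shFABP4 1 were planned. YAP and TAZ target genes, which respond to Hippo signalling, were the only list to pass camera when shFABP4 1 was left out, with 17 of 23 members called higher and 3 lower in shFABP4 2 (adjusted p = 0.00653). AJUBA had 52 and 76 fragments in pLKO and 1086 in shFABP4 2, PTPN14 216 and 329 against 2420, and CCN2, a secreted matrix protein, 333 and 492 against 1908. ANKRD1 went the other way, at 48 and 72 against 16. The same list was lower without shFABP4 2 (adjusted p = 7.33e-05) and did not pass with all libraries (0.171), or with an estimated correlation (adjusted p = 0.754 with all libraries).

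Interferon-stimulated genes had 19 of 34 members called higher and 6 lower in shFABP4 2 without passing as a list (adjusted p = 0.0779). IFIT3 had 105 and 211 fragments in pLKO and 122 and 3026 in shFABP4, and IFITM3 191 and 265 against 203 and 3323. ISG15 had 1629 and 2452 against 101 and 2435. These are raw counts from libraries of unequal depth. Scaled among high-signal genes, ISG15 was lower in both, at log2 ratios to pLKO of -0.33 in shFABP4 1 and -0.49 in shFABP4 2. The genes named from both lists were chosen after their values were seen. With all libraries the list had an adjusted p of 0.112 in camera. It went the other way without shFABP4 2, with a median difference of log2 CPM of -0.33, against 0.82 without shFABP4 1.

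Of 15301 genes tested, 10242 differed between shFABP4 2 and the pLKO libraries. GC content and transcript length bias alone leaves this in place, since 9211 genes were called after the correction, against 9380 among genes with a GC value before it. That the pLKO libraries vary less than separate cultures do cannot be told apart from a difference between the groups. With the spread of the shFABP4 libraries 116 high-signal genes were called, but that spread also holds the background of shFABP4 1, and no label says how the cultures were made.

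Both shFABP4 libraries moved the same way from the pLKO libraries in high-signal genes (r = 0.808 and rho = 0.801 across genes, which are not independent, covariance 0.769, same sign 80.8%). In 100 simulations of unchanged groups against the same controls the mean covariance was 0.0018, the mean r 0.0175 and the same-sign share 50.5%. The measured noise of the pLKO libraries lends a covariance of 0.001506. Each gene and library was simulated independently, so the simulations show only what the shared controls lend. They cannot speak to a bias common to both shFABP4 libraries. They also left out the choice of genes, made partly by shFABP4 2, and the background of shFABP4 1. Together these may raise the correlation and the shared increases, and how much was not tested. Removing GC and length trends left r = 0.764, while 325 genes were called higher in both comparisons (176 for independent lists) and 340 lower (188), part of which may come from the shared controls, as 2 libraries cannot be split. A deviation common to both pLKO libraries was not measured. FABP4 knockdown and another difference between the infected cultures cannot be told apart, since the pLKO libraries held 7 FABP4 fragments together.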
